A study of Shewanella baltica OS155 and Shewanella baltica OS185 and Shewanella baltica OS195 with 72 samples.

How the data were processed

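RNA of 4 strains of the bacterium Shewanella baltica, OS155, OS185, OS195 and OS223, was measured on 2-colour oligonucleotide microarrays. Per the labels' protocols, the strains were grown separately at 25 °C in a defined medium with glucose to an OD600 of 0.400, total RNA was enriched for mRNA, and amplified RNA was labelled with Alexa 555 or Alexa 647. The 72 samples, 18 per strain, are the channels of 36 arrays. Each of the 6 pairs of strains shared 6 arrays, 3 in each dye orientation. The labels say that cultures were grown separately but not whether this holds for the replicates of a strain. Nothing says that replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

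The deposited scanner files give, per the file headers, the median foreground and local background intensity of every spot and the SD of the background. Nothing had been subtracted from these deposited intensity columns, and the highest value was 65535, the limit of the scanner. The files mark no control spots. The flag for a spot that was not found, -50, occurred on 14 arrays, on up to 85.2% of the spots of an array, and no other flag was set. It fell on all 6 arrays of OS223 with OS155, on 80.6% to 85.2% of spots. It also fell on all 6 arrays of OS223 with OS195, on 58.5% to 74.2% of spots. An array of OS155 with OS185 had it on 55.4% and an array of OS223 with OS185 on 46.6%. Arrays of OS195 with OS185 or with OS155 did not carry it. The authors' series matrix holds log2 values for 5515 features. Set against the scanner files, these deposited log2 values follow the mean over a feature's spots of log2(foreground minus background), with a median r of 0.986 (lowest 0.928), a median slope of 0.975, a floor of 1 and each row centred on a median of 0. The column medians of the 72 samples lay between -0.13 and 0.049. What normalization the authors applied beyond this is not given in the sources used here.

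An array carries 30000 spots in 160 columns and 188 rows, named for 6653 features. There are 5635 gene features and 1018 intergenic features. Each ID starts with a strain, called here its source: 4192 gene features have OS185 as source, 501 OS195, 507 OS223 (120 of them on contigs) and 435 OS155. The IDs hold a running number and no gene name. None of them matched the 4661 genes of the reference table of strain OS678, so features are given by ID, and the 27 gene lists fixed beforehand had 0 members and were not tested. The source strain took their place as a grouping of features. That grouping was chosen after the files were opened.

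The placement of the names was tested against the spots before any comparison of strains. If names and spots match, the spots of one feature should have similar levels. The within-feature correlation of mean log2 levels (intraclass correlation, intensities floored at 20) was 0.00369 with the names as deposited, inside the range of -0.0138 to 0.0108 from 100 shuffles of the names. For each array, 196 placements were scored, 4 orientations with shifts of up to 3 spots each way. On all 36 arrays the names turned by 180 degrees scored best, 34 with no shift and 2 with a shift of 1 spot. With those placements the correlation of mean levels was 0.756. On simulated grids the search recovered 6 of 6 placements. The main values therefore use turned names, a choice made after seeing the data on a criterion that does not use the strain labels. Names as deposited are given as an alternative. Turning leaves 16 names at the edge without a spot.

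Intensities were background-corrected with normexp (offset 50), normalized within arrays by loess and between arrays by Aquantile in limma 3.58.1 (R 4.3.3), split into log2 values per channel, and averaged over the spots of a feature. The 5630 gene features with a value on every array (5 had none on some array) were fitted in limma with strain and dye as fixed terms and the array as a random block (consensus correlation 0.564). All 6 pairwise contrasts came from this fit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The number of called features that also differed 2-fold or more is given beside it. Because the fit weighs differences within an array more than differences between arrays, its estimates can be smaller than the difference of the strain means. The 1006 intergenic features with complete values were fitted separately with the same correlation. Permutation tests of class means used 100000 draws, and tests over the 6 arrays of a pair enumerated all sign changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

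On 5630 simulated features with the fitted spread, in which 50 features each were set 0.25, 0.5, 1 or 2 log2 units higher in OS195, the contrast of OS195 with OS185 recovered 9, 40, 47 and 50 of them and called 6 unchanged features. The simulation held an array effect but no slide series, no effect of the partner strain and no correlation between features. Its 6 false calls therefore do not give the error rate in these data. A spot counted as above background when its foreground exceeded the local background by 2 background SDs, and a feature as detected in a sample when at least 50% of its spots did. A strain detected a feature when at least 9 of its 18 samples did. The number of arrays and the signal over background limit the precision. A feature detected in few samples of a strain is near background there, so its fitted difference may understate the true one.

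Slide numbers fall into 3 series, called A (9 arrays), B (15) and C (12), each holding all 4 strains, so the counts of calls are also given with the series as a block and within each series. Not every pair shared an array in each series. Series A held 0 arrays of OS195 with OS185, and series B 0 of OS223 with OS185. Series A and C held 0 arrays of OS223 with OS155 or with OS195. In these cases the contrast within the series is indirect, through arrays with other strains. For intergenic features these fits kept the correlation of the pooled fit. Same-numbered samples of different strains were not treated as pairs. The rule for single features, for files that give no gene names, was the 2 that rose and the 2 that fell most in each pair, by ID, among features called, 2-fold or more apart and of one sign on all 6 arrays of the pair. A feature with no spot above background in any sample of a strain has only a bound there: the bright strain's mean against the dim strain's mean of, per sample, the higher of the lowest signal among spots above background and the feature's own value.

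Alternatives fixed before the data were examined were no background correction, loess alone, quantile normalization, leaving out dim probes, the median of probes, log ratios per array, no array block, no dye term, the replicate number as a block, slide series as a block, each series alone, averages per strain and series, array weights and the authors' log2 values. Chosen after seeing the data were names as deposited, turned names without the shift, leaving out the shifted arrays, series B or the arrays with OS155, loess on OS185-source spots, leaving out spots flagged as not found, and using only the arrays that a pair shared.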

Results

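The series compared the RNA signal of 4 strains of Shewanella baltica, a marine bacterium, grown under one condition. A low signal can mean a low transcript level or a gene that the strain lacks or that its probes match poorly. The features were not checked against the strains' genomes, so these cannot be told apart. Features that rose, fell, or were higher or lower below did so in signal. Samples numbered 18 per strain. The share of spots above background was 36% ± 9.33 (SD, n = 18) in OS185, 29.8% ± 10.6 in OS195, 22.3% ± 10.6 in OS223 and 15.0% ± 9.29 in OS155. The slide series differ in this share and in their mix of strains, with 12 of 18 OS223 samples but 2 OS185 samples in series B. In series A the share was 43.7% in OS185, 42.6% in OS195, 41.6% in OS223 and 24.5% in OS155. In series B it was 24.0%, 23.1%, 17.3% and 5.97%, and in series C 33.8%, 32%, 22.9% and 19.0%. The median correlation between samples of one strain, across gene features, was 0.912 for OS185, 0.878 for OS195, 0.847 for OS223 and 0.678 for OS155.

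Spots that carry one feature's name in the scanner files had unrelated levels as deposited. They had similar levels after the names were turned by 180 degrees on the grid, on every one of the 36 arrays, with a within-feature correlation per array of 0.144 to 0.794 (median 0.526). With names as deposited it lay between -0.00275 and 0.00925. The authors' log2 values followed the names as deposited (median r 0.986) and not the turned names (median r -0.000616). All feature levels below use the turned names.

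**Figure D1:**
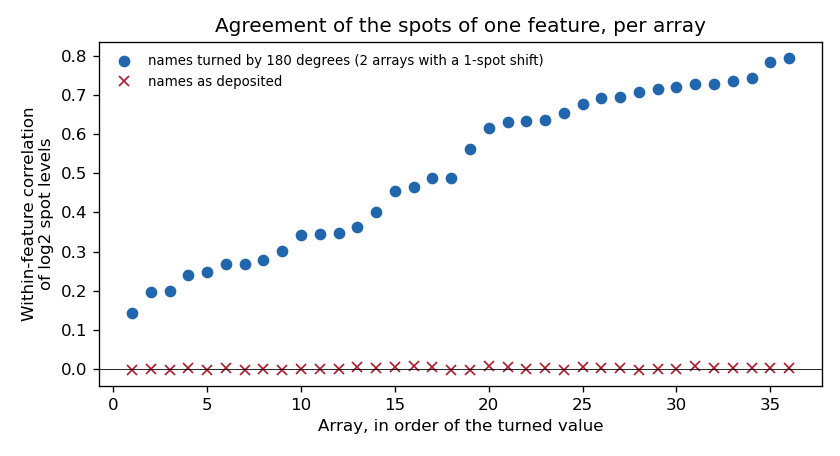
Within-feature correlation of log2 spot levels (y axis) on each of the 36 arrays (x axis, ordered by value). Circles show names turned by 180 degrees, between 0.144 and 0.794, and crosses show names as deposited, at most 0.00925.

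Gene features named for a strain were brightest in that strain for OS195 and OS223. The 500 OS195-source features had a mean log2 intensity of 9.51 ± 0.15 (SD, n = 18) in OS195, against 8.07 ± 0.26 in OS185, 8.43 ± 0.31 in OS223 and 8.69 ± 0.53 in OS155. In OS195 38.8% ± 14.1 of these features were detected per sample, in OS185 6.71% ± 5.94, in OS223 5.50% ± 3.56 and in OS155 7.94% ± 11.1. The 505 OS223-source features had a mean of 9.45 ± 0.14 in OS223, against 8.02 ± 0.29 in OS185, 8.15 ± 0.33 in OS195 and 8.50 ± 0.60 in OS155. Per sample 30.2% ± 10.5 of them were detected in OS223, 7.23% ± 12.2 in OS185, 3.56% ± 2.92 in OS195 and 2.04% ± 2.00 in OS155. The 4190 OS185-source features, whose mean the normalization largely sets since they make up most of the array, were at 9.54 ± 0.054 in OS185, 9.36 ± 0.060 in OS195, 9.33 ± 0.072 in OS223 and 9.36 ± 0.11 in OS155. OS155-source features were hardly detected anywhere: 0.498% ± 0.441 of the 435 features per OS155 sample, and between 0.409% and 0.549% on average in the other strains.

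**Figure D2:**
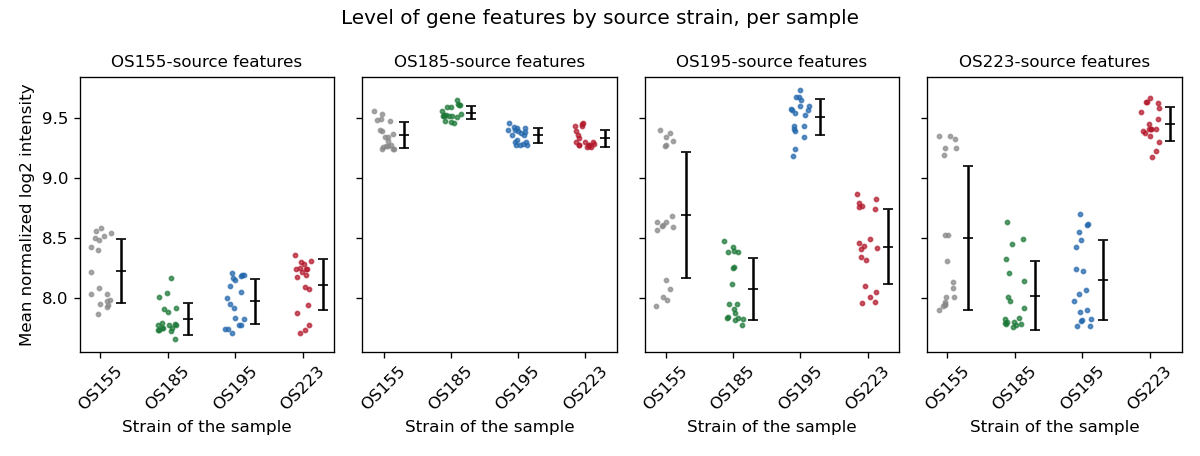
Mean normalized log2 intensity (y axis) of the gene features of each source strain (panels) in each sample (points), by the strain of the sample (x axis); bars show mean and SD of 18 samples. OS195-source features averaged 9.51 in OS195 and 8.07 in OS185, and OS223-source features 9.45 in OS223 and 8.02 in OS185.

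OS195 was compared with OS185 to describe which features set these strains apart. OS195-source features were higher in OS195: 392 of 500 rose against OS185, 228 of them 2-fold or more, and 0 fell. Their class mean was higher on 6 of 6 arrays that held both strains, by 1.05 ± 0.25 log2 units (SD, n = 6; exact sign-flip test, two-sided p = 0.0312, the smallest that 6 arrays allow; adjusted p = 0.0357 over 24 class tests). Over all samples the class differed by 1.44 (permutation test of 18 against 18 samples, p = 1e-05, the smallest possible; adjusted p = 2.4e-05), by 1.40 with slide series as a block, and by 1.69, 1.16 and 1.35 within series A, B and C. Of 4190 OS185-source features 1334 were lower in OS195, 262 of them 2-fold or more, and 754 were higher, 61 of them 2-fold or more. The feature OS195__4037_@gene5248 was at 14.56 ± 1.22 in OS195 and 9.26 ± 2.10 in OS185 (fitted difference 3.61, SE 0.45, limma adjusted p = 2.28e-10). It was detected in only 6 OS185 samples. OS195__4533_@gene5290, with 1 spot, was higher by 3.51 (SE 0.26), against a spot above background in only 2 OS185 samples. OS185__2807_@gene4630 was at 9.48 ± 2.44 in OS195 and 15.23 ± 0.60 in OS185 (fitted difference -3.58, SE 0.53, limma adjusted p = 2.95e-08). OS185__2004_@gene4478, with 1 spot, was lower by a fitted -3.09 (SE 0.28), against a spot above background in only 1 OS195 sample and in 18 OS185 samples. OS185__2807_@gene4630 was detected in 8 OS195 samples. In all, limma called 2540 of 5630 gene features, 1198 higher and 1342 lower in OS195, of which 297 and 262 differed 2-fold or more. Of the called features 1635 were detected in at least 1 of the strains, 621 of them higher and 1014 lower. With slide series as a block 2555 features were called, and within series A, B and C alone 1139, 811 and 2153. Within series A 613 were higher and 526 lower in OS195, the other way from the pooled fit. Series A held 0 arrays with both strains, so its contrast is indirect. Series B, with 373 and 438, and series C, with 1022 and 1131, went the same way as the pooled fit. With loess fitted on OS185-source spots only, an alternative chosen after seeing the data, 57.6% of the calls were higher in OS195, against 47.2% here; with spots flagged as not found left out, 56.5% were.

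OS223 was compared with OS185 in the same way. Of 505 OS223-source features 387 rose in OS223, 220 of them 2-fold or more, and 0 fell. The class mean was higher in OS223 on 6 of 6 shared arrays, by 1.00 ± 0.30 (SD, n = 6; exact sign-flip p = 0.0312, adjusted p = 0.0357). Over all samples it differed by 1.43 (permutation p = 1e-05), by 1.32 with slide series as a block, and by 1.13, 1.41 and 1.41 within series A, B and C. Among OS185-source features 1220 were lower in OS223, 162 of them 2-fold or more, and 398 were higher, 35 of them 2-fold or more. The feature OS223__3623_@gene5991, represented by 1 spot, was at 13.15 ± 0.82 in OS223 and 8.07 ± 0.77 in OS185 (fitted difference 4.15, SE 0.27, limma adjusted p = 2.52e-21), and was above background in 16 OS223 samples and 2 OS185 samples. OS223_Contig66_48_@gene5494, with 1 spot, was higher by 3.96 (SE 0.36) and was detected in only 5 OS185 samples. OS185__2807_@gene4630 was lower in OS223 by a fitted -3.38 (SE 0.53), and OS185__844_@gene4354 was at 9.07 ± 1.18 in OS223 and 12.90 ± 0.51 in OS185 (fitted difference -2.86, SE 0.31). Each of these 2 was detected in only 5 OS223 samples. Within slide series A alone neither was called: the differences were -0.20 (limma adjusted p = 0.953) and -0.87 (adjusted p = 0.721). With samples averaged by strain and series, OS185__2807_@gene4630 was at -3.67 and not called either (adjusted p = 0.141). limma called 2203 gene features, 973 higher and 1230 lower in OS223, of which 271 and 164 differed 2-fold or more. Of the called features 1252 were detected in at least 1 of the strains, 348 of them higher and 904 lower. With slide series as a block the count was 1797, and within series A, B and C alone it was 499, 590 and 994. Unlike in the pooled fit, higher features were not outnumbered within a series. Higher and lower in OS223 were 352 and 147 in A, 296 and 294 in B, and 499 and 495 in C. Series B held 0 arrays with both strains, so its contrast is indirect. With loess on OS185-source spots only, 59.3% of the calls were higher in OS223, against 44.2% here; with spots flagged as not found left out, 70.1% were higher and the median of all features moved from 0.017 to 0.13.

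Between OS223 and OS195, both own-source classes differed. OS223-source features were higher in OS223 (345 of 505 rose, 199 of them 2-fold or more), and OS195-source features were lower (318 of 500 fell, 178 of them 2-fold or more). On the 6 shared arrays the class means differed by 0.86 ± 0.08 and -0.67 ± 0.07 (SD, n = 6), each with 1 sign on all 6 arrays (exact sign-flip p = 0.0312, adjusted p = 0.0357). These arrays all lie in series B, and 58.5% to 74.2% of their spots were flagged as not found. Over all samples the differences were 1.30 and -1.08 (permutation p = 1e-05 for each). They were 1.21 and -1.13 with slide series as a block. Within series A, B and C the first was 1.52, 1.06 and 1.36 and the second -1.58, -0.89 and -1.33. OS185-source features went both ways, with 781 higher in OS223 and 905 lower, 96 of them 2-fold or more in either direction. Higher in OS223 were OS223__3623_@gene5991, with a fitted difference of 4.37 (SE 0.27) against a spot above background in only 1 OS195 sample, and OS223__483_@gene5643, at 14.37 ± 0.55 in OS223 and 8.74 ± 1.34 in OS195 (fitted difference 4.13, SE 0.41, limma adjusted p = 6.5e-14). Lower were OS195__4037_@gene5248, with a fitted difference of -3.74 (SE 0.45), and OS195__2237_@gene1830, at 8.92 ± 1.25 in OS223 and 14.73 ± 0.95 in OS195 (fitted difference -3.65, SE 0.49). These 2 features were each detected in only 4 OS223 samples, and OS223__483_@gene5643 in only 4 OS195 samples. limma called 2391 gene features, 1164 higher and 1227 lower, of which 297 and 274 differed 2-fold or more. Of the called features 1289 were detected in at least 1 of the strains, 578 of them higher and 711 lower. The count was 2469 with slide series as a block and 905, 1641 and 1147 within series A, B and C alone. With spots flagged as not found left out, 59.6% of the calls were higher in OS223, against 48.7% here.

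**Figure D3:**
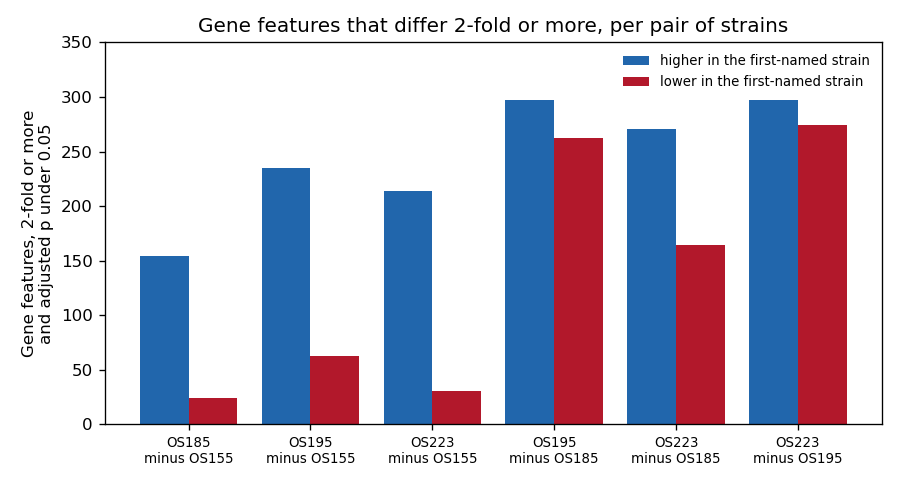
Number of gene features (y axis) called by limma and 2-fold or more apart, for each pair of strains (x axis); blue bars are higher and red bars lower in the first-named strain. The pairs without OS155 have 271 to 297 higher and 164 to 274 lower features; the pairs with OS155 have 154 to 235 higher and 24 to 63 lower.

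The libraries labelled OS155 followed the strain on the other channel of their array. On 6 arrays shared with OS195, OS195-source features averaged 9.33 ± 0.054 (SD, n = 6) in the OS155 channel, and on the other 12 arrays 8.37 ± 0.31 (difference 0.95, exact permutation test p = 5.39e-05, adjusted p = 6.46e-05 over 6 such tests). Beside OS223, OS223-source features averaged 9.29 ± 0.066 in the OS155 channel, against 8.11 ± 0.22 elsewhere (difference 1.18, exact permutation p = 5.39e-05). These tests exchange samples across slide series. The first difference was 1.30, 0.78 and 1.24 within slide series A, B and C, with only 1 sample beside OS195 in B. The second could be read in series B alone, where it was 0.76. All 6 samples beside OS223 lie there, against replicates 15 and 16. In the other strains the difference was 0.43 to 0.62 over all series. Within a series it was 0.17 (B, 1 sample against 1) and 0.48 (C) for OS185 beside OS195. For OS185 beside OS223 it was 0.70 (A) and 0.26 (C). It was 0.37 (B) for OS223 beside OS195 and 0.41 (B) for OS195 beside OS223. The share of the partner's signal that a channel showed on bright partner-source spots was divided by the same share on OS185-source spots of its array. This ratio was 0.470 to 0.766 in 12 OS155 samples (median 0.653) and 0.00551 to 0.445 in 24 samples of the other strains (median 0.147). Before this division and without normalization, the share on partner-source spots was 0.079 to 0.52 in OS155 and 0.0073 to 0.41 in the other strains. Loess within arrays draws a dim channel toward its partner. It may therefore add to the rise in the normalized levels, which was not tested. Mean log ratios per feature from opposite dye orientations correlated at 0.531 to 0.605 across features in the 3 pairs with OS155 and at 0.846 to 0.851 in the other 3. The comparisons with OS155 below carry this limit, and the other 3 pairs carry it to a lesser degree. There too the own-source classes differed less on shared arrays than over all samples. In OS195 minus OS185 the OS195-source class differed by 1.05 against 1.44. Of its shared arrays 1 lies in series B and 5 in series C, where all samples gave 1.16 and 1.35. In OS223 minus OS195 the OS223-source class differed by 0.86 against 1.30. Its 6 shared arrays all lie in series B, where all samples gave 1.06. Part of these gaps thus goes with slide series.

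**Figure D4:**
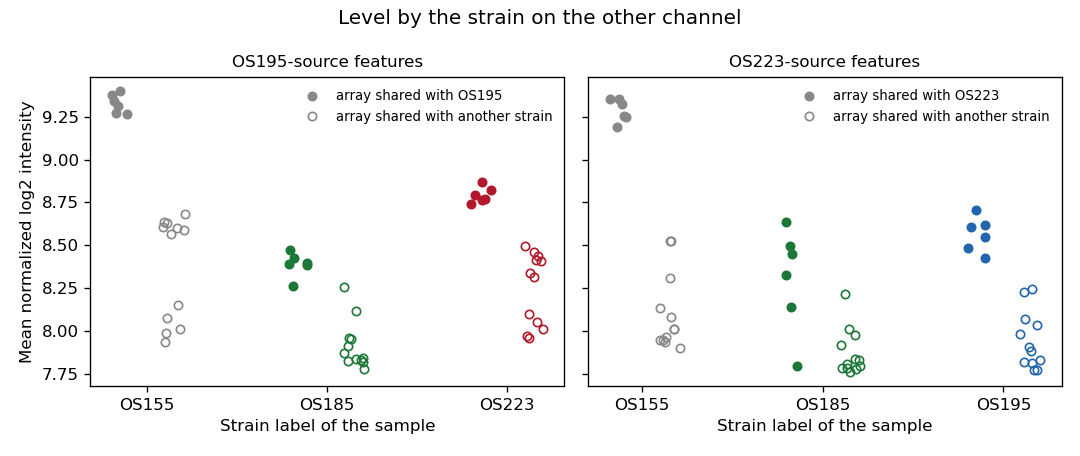
Mean normalized log2 intensity (y axis) of OS195-source (left) and OS223-source (right) features in samples of the other strains (x axis). Filled points are samples whose array also held the source strain and open points all other samples; the filled OS155 points average 9.33 and 9.29.

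Against the libraries labelled OS155, OS185 was higher for 1355 OS185-source features and lower for 509, and 153 and 16 of these differed 2-fold or more. OS185__844_@gene4354 was at 12.90 ± 0.51 in OS185 and 9.34 ± 1.89 in OS155 (fitted difference 2.60, SE 0.31, limma adjusted p = 2.54e-10), and OS185__2924_@gene4647 was higher by 2.23 (SE 0.23). Each was detected in only 5 OS155 samples. OS185__3994_@gene3731, with 1 spot, was at 10.59 ± 0.66 in OS185 and 13.05 ± 0.76 in OS155 (fitted difference -2.26, SE 0.16), and OS185__954_@gene3210 was lower in OS185 by a fitted -1.86 (SE 0.27). Within slide series A alone OS185__844_@gene4354 (1.84, limma adjusted p = 0.202), OS185__2924_@gene4647 (1.60, adjusted p = 0.103) and OS185__954_@gene3210 (-1.28, adjusted p = 0.140) were not called. OS185__954_@gene3210 was not called within series B either (-2.12, adjusted p = 0.0801), nor with samples averaged by strain and series (-2.28, adjusted p = 0.0617). limma called 2911 gene features, 1361 higher and 1550 lower, of which 154 and 24 differed 2-fold or more. The lower calls included 324 of 435 OS155-source, 387 of 500 OS195-source and 330 of 505 OS223-source features. Of these classes 0, at most 9 and at most 3 features were detected in at least 9 samples of either strain. On the 6 shared arrays the 3 class means differed by -0.21, -0.20 and -0.20. The cause was not tested. Only 1274 of the called features were detected in at least 1 of the strains, and of these 1155 were higher and 119 lower in OS185. The count was 2653 with slide series as a block, but 200, 692 and 724 within series A, B and C alone, and 259 on the 6 shared arrays alone. Unlike in the pooled fit, more were higher than lower in OS185 within each series and on the shared arrays. They were 142 and 58 in A, 421 and 271 in B, 470 and 254 in C, and 209 and 50 on the shared arrays. With loess on OS185-source spots only, 34.3% of the calls were higher in OS185, against 46.8% here, and the median of OS185-source features was 0.018, against 0.092 here.

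OS195 was higher than the libraries labelled OS155 for 291 of 500 OS195-source features, 133 of them 2-fold or more, and lower for 31. On the 6 shared arrays the class mean was higher by 0.30 ± 0.043 (SD, n = 6; exact sign-flip p = 0.0312, adjusted p = 0.0357), against 0.82 over all samples (permutation p = 1e-05), 0.81 with slide series as a block and 0.93, 0.79 and 0.76 within series A, B and C. OS195__3004_@gene5179 was at 13.00 ± 0.46 in OS195 and 9.32 ± 1.83 in OS155 (fitted difference 2.79, SE 0.27, limma adjusted p = 8.05e-14), and OS195__4609_@gene5314 was higher by 2.74 (SE 0.22). Each was detected in only 6 OS155 samples. OS185__954_@gene3210 was at 10.48 ± 1.41 in OS195 and 14.25 ± 0.98 in OS155 (fitted difference -2.92, SE 0.27), and OS185__3731_@gene764, with 1 spot, was lower by a fitted -2.85 (SE 0.27). They were detected in 12 and 8 OS195 samples. Within slide series A alone these 2 features were at -1.36 (limma adjusted p = 0.150) and -1.61 (adjusted p = 0.0813) and not called. Of 4190 OS185-source features 934 were higher and 827 lower in OS195. limma called 2530 gene features, 1235 higher and 1295 lower, of which 235 and 63 differed 2-fold or more, and 1093 of the called features were detected in at least 1 of the strains, 851 of them higher and 242 lower. The count was 2732 with slide series as a block, 446, 1872 and 266 within series A, B and C alone, and 798 on the shared arrays alone. Unlike in the pooled fit, more were higher than lower in OS195 within each series and on the shared arrays. They were 316 and 130 in A, 970 and 902 in B, 171 and 95 in C, and 515 and 283 on the shared arrays. Of the calls 48.8% were higher in OS195 here, 42.0% with loess on OS185-source spots only and 56.7% with spots flagged as not found left out.

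OS223 was higher than the libraries labelled OS155 for 271 of 505 OS223-source features, 157 of them 2-fold or more, and lower for 12. The class mean was higher by 0.33 ± 0.069 on the 6 shared arrays (SD, n = 6; exact sign-flip p = 0.0312, adjusted p = 0.0357), by 0.95 over all samples (permutation p = 1e-05), by 0.79 with slide series as a block and by 1.35, 0.42 and 1.18 within series A, B and C. OS223__3623_@gene5991, represented by 1 spot, had a mean of 13.15 ± 0.82 in OS223 and was not above background in any OS155 sample. The bound described for such features gives an at least 10.7-fold higher level. It uses the lowest signal above background in a sample, so a higher limit at this spot would lower it. The limma adjusted p of 2.1e-17 belongs to the fitted difference of 3.46 (SE 0.27). OS223__483_@gene5643 was higher by 3.17 (SE 0.41) and was detected in only 6 OS155 samples. OS185__954_@gene3210 was lower in OS223 by a fitted -3.0 (SE 0.27), and its neighbour by number, OS185__955_@gene3209, was at 9.19 ± 0.43 in OS223 and 11.93 ± 0.95 in OS155 (fitted difference -2.29, SE 0.18). They were detected in 12 and 3 OS223 samples. limma called 1867 gene features, 975 higher and 892 lower, of which 214 and 31 differed 2-fold or more, and 658 of the called features were detected in at least 1 of the strains, 534 of them higher and 124 lower. The count was 2080 with slide series as a block, 959, 1194 and 682 within series A, B and C alone, and 298 on the shared arrays, which all lie in series B. On these arrays 80.6% to 85.2% of spots were flagged as not found. With spots flagged as not found left out, 71.7% of the calls were higher in OS223, against 52.2% here, and the median of all features moved from -0.049 to 0.064. With loess on OS185-source spots only, 45% were higher.

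Features that set 1 strain apart from each of the other 3 by 2-fold or more numbered 420. OS223 was higher for 157, of which 149 had OS223 as source, and OS195 was higher for 146, of which 126 had OS195 as source. OS185 was higher for 78, all with OS185 as source. The libraries labelled OS155 were higher for 11 OS185-source features. Lower features were fewer, 15 in OS195 and 6 in OS223. In OS185 they were OS195__2802_@gene5126, OS195__4518_@gene5280 and OS223_Contig67_44_@gene5490, and in OS155 OS185__1316_@gene1157, OS185__3086_@gene2841, OS185__3151_@gene2906 and OS185__3604_@gene707, all named here after their values were seen. No OS155-source feature was among the 420. The count was 417 with slide series as a block and 303, 417 and 453 within series A, B and C alone. The count for OS185, higher and lower together, was 81, and 5, 144 and 127 within series A, B and C. That for OS195 was 161, and 73 and 57 within series A and C. That for OS223 was 163, and 83 and 256 within series B and C. That for OS155 was 15, and 6 within series A. With names as deposited, an alternative chosen after seeing the data, the count was 62. Over all strains the limma F test called 4293 of 5630 gene features, 4218 with slide series as a block, and 1665, 2.6e3 and 2.6e3 within series A, B and C alone.

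Of 1006 intergenic features 334 were called by the F test, 322 with slide series as a block, and 117, 142 and 165 within series A, B and C alone. Of 148 OS223-source intergenic features 47 rose in OS223 against OS185 and 41 against OS195, and 0 fell in either comparison (median fitted differences 0.34 and 0.27). With slide series as a block these were 39 and 40, and within series A, B and C 23, 10 and 20 against OS185 and 21, 24 and 17 against OS195. Of 153 OS195-source intergenic features 62 rose in OS195 against OS185, 29 of them 2-fold or more (median 0.41), and 49 fell in OS223 against OS195, 26 of them 2-fold or more (median -0.24). With slide series as a block these were 58 and 50, and within series A, B and C 41, 13 and 57 rose and 17, 30 and 15 fell. The median of the 546 OS185-source intergenic features had the opposite sign to that of OS185-source gene features in the pairs with OS185: -0.12 against 0.092 in OS185 minus OS155, 0.058 against -0.054 in OS195 minus OS185 and 0.052 against -0.086 in OS223 minus OS185. In OS223 minus OS195 it was 0.019 against -0.0075. It had the same sign in OS195 minus OS155 (-0.11 against -0.012) and in OS223 minus OS155 (-0.085 against -0.029).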

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

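Names as deposited, shared arrays alone, loess on OS185-source spots, leaving out spots flagged as not found, leaving out arrays, and names turned without a shift were chosen after the data were seen; the other alternatives were planned. Of the comparison counts, 134 stayed within 1.5 times the reported count and 52 moved beyond it. Of the values of single features, 496 kept their direction and side of the threshold, 28 kept the direction and lost the threshold, and 24 changed sign. Of the 28, 9 did so with names as deposited, 9 with the authors' log2 values, 7 within series A, 1 within series B and 2 averaged by strain and series; those from the series and averages stand beside their features in the report. Of the medians of own-source features, 75 moved by less than the SD between arrays, 63 by more and 4 changed sign. Signal over background limits the rest: with dim probes left out, judged over the samples of all strains together, only 1995 features could be tested.

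Counts below are given in the order OS185 minus OS155, OS195 minus OS155, OS223 minus OS155, OS195 minus OS185, OS223 minus OS185 and OS223 minus OS195. With dim probes left out they were 1053, 1252, 1176, 1123, 684 and 1169, with 1740 overall and 135 strain-distinct, fewer features being tested. This filter judged a probe over the samples of all strains together, so it left out probes above background in a single strain only. A drop in strain-distinct features is thus built into it. The strain-distinct counts under it, in all and by strain, cannot show whether those features hold. Under this filter the percent higher was 75.8, 68.0 and 75.3 in the pairs with OS155. Within slide series A they were 200, 446, 959, 1139, 499 and 905, with 1665 overall. Within series B the counts that moved were 692, 1194, 811 and 590 (OS185 minus OS155, OS223 minus OS155, OS195 minus OS185, OS223 minus OS185), with 2.6e3 overall. Within series C they were 724, 266, 682, 994 and 1147 (all pairs but OS195 minus OS185), with 2.6e3 overall. Averaged by strain and series they were 183, 367, 273, 1171, 577 and 1159, with 1401 overall. These settings hold fewer samples. The authors' log2 values gave 588, 610, 658, 1070, 957 and 1169, with 2268 overall. Shared arrays alone gave 259, 798 and 298 for the pairs with OS155, 1457 for OS223 minus OS185 and 1541 for OS223 minus OS195, with 121 strain-distinct. Names as deposited gave 1079 for OS185 minus OS155 and 1455 for OS195 minus OS155, with 62 strain-distinct. Leaving out spots flagged as not found gave 1529 for OS185 minus OS155. By strain, strain-distinct features numbered 31, 16, 61 and 27 in OS155, OS185, OS195 and OS223 with dim probes left out, against 15, 81, 161 and 163. With names as deposited they numbered 5, 8, 30 and 19, and on shared arrays alone 17, 35 and 57 in OS185, OS195 and OS223. In OS155 they numbered 26 with quantile normalization, 7 averaged by strain and series and 37 with the authors' log2 values. In OS185 they numbered 52 with log ratios per array and 168 without an array block, and in OS223 93 without background correction and 275 without spots flagged as not found. Over all strains, they numbered 272 without background correction and 652 without an array block. For these the cause was not tested.

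Signs changed only under the authors' log2 values and names as deposited, which both use the unturned names; values are given in that order. In OS185 minus OS155, OS185__844_@gene4354 was at -0.10 and -0.045 and OS185__3994_@gene3731 at 3.30 and 1.26. In OS195 minus OS155, OS195__3004_@gene5179 was at -0.84 and -0.19 and OS185__3731_@gene764 at 0.12 and 0.061. In OS223 minus OS155, OS223__483_@gene5643 was at -0.77 and -0.21 and OS185__955_@gene3209 at 0.24 and 0.15. In OS195 minus OS185, OS195__4037_@gene5248 was at -1.33 and -0.35 and OS185__2807_@gene4630 at 0.72 and 0.21. In OS223 minus OS185, OS223__3623_@gene5991 was at -0.93 and -0.59. In OS223 minus OS195, OS223__483_@gene5643 was at -0.61 and -0.17, OS195__4037_@gene5248 at 0.48 and 0.068 and OS195__2237_@gene1830 at 1.03 and 0.49. The median of OS223-source features in OS223 minus OS155 was -0.032 and -0.040. With names as deposited it was -0.0062 in OS223 minus OS195, and that of OS195-source features in OS195 minus OS155 was -0.0021.

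Samples share only a number: 49 of 104 same-number pairs correlated above 0.1, and 5 of 72 samples correlated best with their own number off their array. With the replicate number as a block the counts were 3078, 2454, 1780, 2794, 2855 and 2555, with 4543 overall and 519 strain-distinct, none beyond 1.5 times the reported count. Keeping spots with bad flags was not run, since no spot carried one, and the gene list tests could not be run, since no list had members.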

Other observations

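The tests of name placement, of the libraries labelled OS155 and of neighbouring IDs in this part were chosen after the results were seen; the regroupings of samples were planned.

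OS185-source features with neighbouring ID numbers differed together. The 15 features numbered 2920 to 2934 averaged 11.47 ± 0.26 (SD, n = 18) in OS185, against 8.45 ± 0.72 in OS195, 8.72 ± 0.82 in OS223 and 9.16 ± 1.20 in OS155. All 15 were detected in at least 9 of 18 OS185 samples, and 0 were in each of the other strains. The 6 features numbered 952 to 957 were highest in the libraries labelled OS155, at 11.52 ± 0.78, against 10.16 ± 0.51 in OS185, 9.25 ± 0.69 in OS195 and 9.26 ± 0.45 in OS223. By detection they did not stand out there: 3 of the 6 were detected in at least 9 OS155 samples and 5 in at least 9 OS185 samples. Both runs were chosen after their values were seen.

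Differences between OS195 and OS185 correlated at 0.406 between neighbouring IDs, against at most 0.0553 in 1000 shuffles. Nearness on the slide was argued against, since the correlation was still 0.406 for neighbours over 20 spots apart. Of 706 OS185-source features whose gene number lies above 4149, the highest among OS155-source features, 17.3% were 2-fold or more lower in OS195 than in OS185, against 4.02% of the other 3484. Shifting the ID order 1000 times gave at most 99 such features, against the 122 seen (permutation p = 0.000999, the smallest possible, adjusted p = 0.0024). This was 1 of 12 such tests, over 6 pairs and 2 directions, of which 7 passed and 5 did not. Lower in OS185 against OS155 were 0% against 0.459% (p = 1), lower in OS195 against OS155 0.567% against 1.61% (p = 0.931) and lower in OS223 against OS155 0.708% against 0.689% (p = 0.483); higher in OS195 against OS185 (p = 0.151) and in OS223 against OS195 (p = 0.117) did not pass either. The numbers above 4149 may mark genes that not all strains carry, which was not tested against the strains' genomes.

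Spots of one feature had unrelated levels under the deposited names. Noise alone was argued against, since the OS195 minus OS185 difference per position correlated at 0.818 between slide series A and C. Turning the names by 180 degrees gave a within-feature correlation of 0.756. A turned name grid is the likely source, and the authors' log2 values then carry it too; no biological explanation was tested.

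The libraries labelled OS155 followed the strain on the same array. OS155 RNA that carries the OS195-source genes does not by itself account for this, since their level in OS155 was higher by 0.95 beside OS195. Whether OS155 carries these genes is not decided by this. Their level was also higher beside OS195 in OS185, by 0.47, and in OS223, by 0.55. In all 3 slide series the OS155 channels beside OS195 or OS223, 12 of 18, were dimmer against their partner on OS185-source spots than the other strains' channels measured there; the 6 beside OS185 were not measured. The ranges on partner-source spots overlapped, in that the lowest OS155 value lay below the highest of the other strains in each series. These ranges pool dyes and partners. With series, partner and dye alike, OS155 was higher beside OS195 with Alexa 647, at 0.224 and 0.361 against 0.120 and 0.154 (C). In series B it was 0.163 there against 0.087 to 0.132. Beside OS223 in series B it was 0.079 to 0.108 against 0.044 to 0.065 with Alexa 555. With Alexa 647 the values overlapped, at 0.095 to 0.191 against 0.077 to 0.146. Whether a weak OS155 signal with a leak common to all strains accounts for this is therefore not decided. In series A these OS155 channels were Alexa 555 beside OS195 and the others Alexa 647 beside OS223. Dye and partner cannot be told apart from strain there. Partner RNA mixed into the OS155 tube stays open, since the scanner gain of each channel is not known. On partner-source spots the OS155 channel reached 0.525, 0.191 and 0.361 of the partner in series A, B and C. The other strains reached 0.409, 0.146 and 0.273.

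For all 8 counts only 1 of 100 splits of the samples, the real one, called as many features. The counts thus exceed what random regroupings of these samples gave. The splits treat samples as independent and break up array pairs and slide series. They cannot exclude a chance difference between cultures, since nothing says that replicates came from separate cultures. The real count and the highest of the other splits were 2911 and 506 for OS185 minus OS155, 2530 and 892 for OS195 minus OS155, 1867 and 231 for OS223 minus OS155, 2540 and 881 for OS195 minus OS185, 2203 and 603 for OS223 minus OS185, and 2391 and 536 for OS223 minus OS195. Over all strains they were 4293 and 125, and for strain-distinct features 420 and 0. Sets that mix the strains average out their differences, so 2-fold gaps are unlikely there and the 0 says little.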
